A study of Homo sapiens with 12 samples.

How the data were processed

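Total RNA from 12 samples labelled as peripheral blood T cells was hybridised to Affymetrix expression arrays, 6 for newly diagnosed pediatric ITP and 6 for remission. The deposited log2 values were made with PLIER, an Affymetrix method that summarises the probes of a probe set into 1 value, per the submitters' processing notes. The background correction, the normalization and the offset are not given in the sources used here. The values, between 4.65 and 12.81, were taken as a log scale from their range, and base 2 was inferred, so differences called log2 here rest on that reading. The sample description and the RNA kit in the labels name adipose or lipid tissue, while the title and the source name T cells; the groups follow the titles, and adipocyte genes were measured as a check.

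The array holds 54675 probe sets. In the annotation, 41097 have 1 gene symbol, 1801 several and 11777 none, and only those with 1 symbol were named. The 62 control probe sets were left out. Because array medians differed by 0.023, under the limit of 0.2 set in advance, the values were used without further normalization. Probe sets whose mean lay at or below the median of all means (5.10) were left out, leaving 27306, of which 21960 have 1 symbol, for 11701 genes. The 24 unspiked bacterial controls had a median of 4.84, which marks the floor, so differences of dim probe sets are compressed. Correlations between arrays ran from 0.951 to 0.991, and no arrays were identical.

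Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The fit without a block, all 26 gene lists, the rule for named genes and a set of other settings were fixed before the data were examined. Of 564 list genes, 515 were on the array. Lists were tested with limma's camera at a preset correlation of 0.01 and at an estimated one, on the probe set with the highest mean per gene, and as mean z-scores per array with an exact permutation test over 924 relabellings, or 64 sign flips for the block. Named genes were up to 10 rises and 10 falls past the threshold by size, filled to 5 per direction by smallest p, up to 4 members of each list past the threshold or else the 2 with the smallest p, and a set reported in all cases, of which 1 gene is not reported here. Genes whose level follows an inherited variant and sex-linked genes were never named. The same rule was applied to the fit with the block. On simulated data with the real arrays' spread, 86% of changes of 1 log2 unit and 49% of changes of 0.5 were recovered without the block, with 4 false calls, and 82% and 47% with the block, with 6 false calls, over 27306 probe sets. The simulated noise was drawn independently for each probe set and held no structure shared between probe sets. These rates therefore need not hold for the real arrays.

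Both groups carry the replicate numbers 1 to 6. The study's design text says that the same children were sampled at both times, but no label says that a number marks one child, so the pairing by number is an inference. Deviations from the group means correlated between same-numbered arrays at -0.21 to 0.54 (mean 0.22, against -0.043 for different numbers), over 0.1 for 5 of 6 numbers but not for number 2. Because each group was centred on its own mean, the mean for different numbers largely follows from that for same numbers and is no separate baseline. In a check for mixed-up samples 5 of 6 number pairs gave the same clear result, none gave 2 different ones, and 1 of 12 libraries was not clear. Beyond these, 2 comparisons with the other ways of pairing were made. In the first, 21 probe sets with separated high and low states matched in 93 of 126 states under the numbers' pairing, against up to 103 under another, and 72 of 720 pairings did as well, so that test did not single out the numbers. It was followed, after that outcome was known, by a second one on 36 probe sets of genes that follow inherited variants, where the mean squared difference was 0.243 under the numbers' pairing, 0.228 under the closest other pairing and 0.441 at the median, with 7 of 720 pairings as close or closer. Neither comparison gave the numbers' pairing as the best one. The blocked counts of calls were first seen together with the correlations above, so the pairing was not judged blind to them. The fit without the block is therefore the reported result, and the blocked values stand beside it. p-values measure only the spread between these samples.

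The bioB hybridisation control split the arrays into a high batch (7.64 to 8.34, newly diagnosed 1, 2, 3 and 5 and remission 4 and 6) and a low batch (5.71 to 6.01, the others). The labels used here name no batch, so these batches are an inference from this control, with the cut at 7. The difference between 3 prime and 5 prime actin controls was 3.04 ± 0.98 in newly diagnosed and 2.66 ± 0.64 in remission arrays (SD, n = 6, exact permutation p = 0.485) and was highest in newly diagnosed 2 (4.82) and remission 5 (3.66). Terms for the batch and the actin control, each batch alone, arrays left out for high actin differences or platelet markers, removal of a trend on gene length, and the settings of the blocked fit other than leaving out each number were chosen after seeing the data. Genomic spans came from the RefSeq annotation of GRCh38.p14, used for names and lengths only, and were known for 99.9% of the tested genes. The settings fixed beforehand were the replicate block, other filters, quantile normalization, median centring, a trended and robust variance, array weights, 1 probe set per gene and leaving out each array. Leaving out each number under the block and the estimated correlation for the lists were also fixed beforehand. The pseudocount alternatives had no use, since the values were already on a log scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.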

Results

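Expression was measured on 12 arrays of T cells isolated from peripheral blood, 6 from children newly diagnosed with immune thrombocytopenia (ITP), an autoimmune loss of platelets, and 6 from remission, which the study's design text places 12 months later in the same 6 children. The question addressed was how T cell expression differs between active disease and remission. All differences are remission minus newly diagnosed on the log2 scale of the deposited values. Array medians lay between 5.08 and 5.11, and the number of arrays limits the precision.

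RORA, which encodes a nuclear receptor that acts in T helper 17 (Th17) cells and innate lymphoid cells, was the gene with the clearest difference. Its most clearly separated probe set rose from 6.37 ± 0.094 to 7.11 ± 0.15 (SD, n = 6 per group), a difference of 0.73 (SE 0.073) that was present in 6 of 6 replicate numbers (limma, Benjamini-Hochberg adjusted p = 0.00775). BRWD3, a bromodomain and WD repeat gene, rose by 0.46 (SE 0.060) from 6.41 ± 0.12 to 6.87 ± 0.061, and CNOT7, a deadenylase subunit of the CCR4-NOT complex, rose by 0.45 (SE 0.062) from 5.17 ± 0.12 to 5.62 ± 0.075 (limma, Benjamini-Hochberg adjusted p = 0.0449 for each). The remaining 2 probe sets past the threshold (differences 0.66 and 0.37) have no gene symbol in the annotation used here. The 6 RORA probe sets tested differed by 0.077 to 0.98 and the 3 of BRWD3 by 0.076 to 0.46, each set in 1 direction, while the 5 of CNOT7 ran from -0.051 to 0.45. The RORA difference at the called probe set was 0.65 within the arrays with a high bioB hybridisation control and 0.73 within those with a low one, and with this batch as a term RORA was the 1 call left (0.69, SE 0.070, limma, Benjamini-Hochberg adjusted p = 0.0211). The call ended in that fit without newly diagnosed 6, with 11 arrays (0.635, SE 0.073, limma, Benjamini-Hochberg adjusted p = 0.132). With no batch term it ended in the 10 arrays without newly diagnosed 2 and remission 5 (0.68, SE 0.074, limma, Benjamini-Hochberg adjusted p = 0.0748). On 1 probe set per gene, where a brighter RORA probe set stands for the gene, none passed (lowest limma, Benjamini-Hochberg adjusted p = 0.0756).

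No probe set fell past the threshold in this fit. The smallest p-values among lower probe sets belonged to FAM174C (-0.41), the proteasome subunit PSMB2 (-0.45), CMTM8 (-0.57), the T and NK cell surface protein CD7 (-0.62) and YIF1A (-0.27), with Benjamini-Hochberg adjusted p from limma between 0.0911 and 0.0924. The 4 PSMB2 probe sets ran from -0.45 to 0.039, and the 5 of TNRC6A from -0.24 to 0.39. TNRC6A (0.39) and AQR (0.49) followed the 3 named rises, with an adjusted p of 0.0745 from limma after Benjamini-Hochberg adjustment. In total 5 of 27306 probe sets passed, while 5219 (19.1%) had an unadjusted p under 0.05 in limma where 1365 were expected by chance, 3432 of them (65.8%) higher in remission. This split moved with the scaling and the filter, to 2955 of 5326 higher (55.5%) with quantile normalization and to 4100 of 8982 (45.6%) with no filter on expression, where most were lower. The count of 5 became 1079 without the newly diagnosed array 4 and 25 without the remission array 2, 3 without newly diagnosed 6, 2 without newly diagnosed 5 or remission 3, and 1 without newly diagnosed 1, 2 or 3 or remission 1, 4 or 6. RORA passed in each of these fits (highest limma, Benjamini-Hochberg adjusted p = 0.0435), while the adjusted p of BRWD3 and CNOT7 in limma with Benjamini-Hochberg adjustment reached 0.16.

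**Figure D1:**
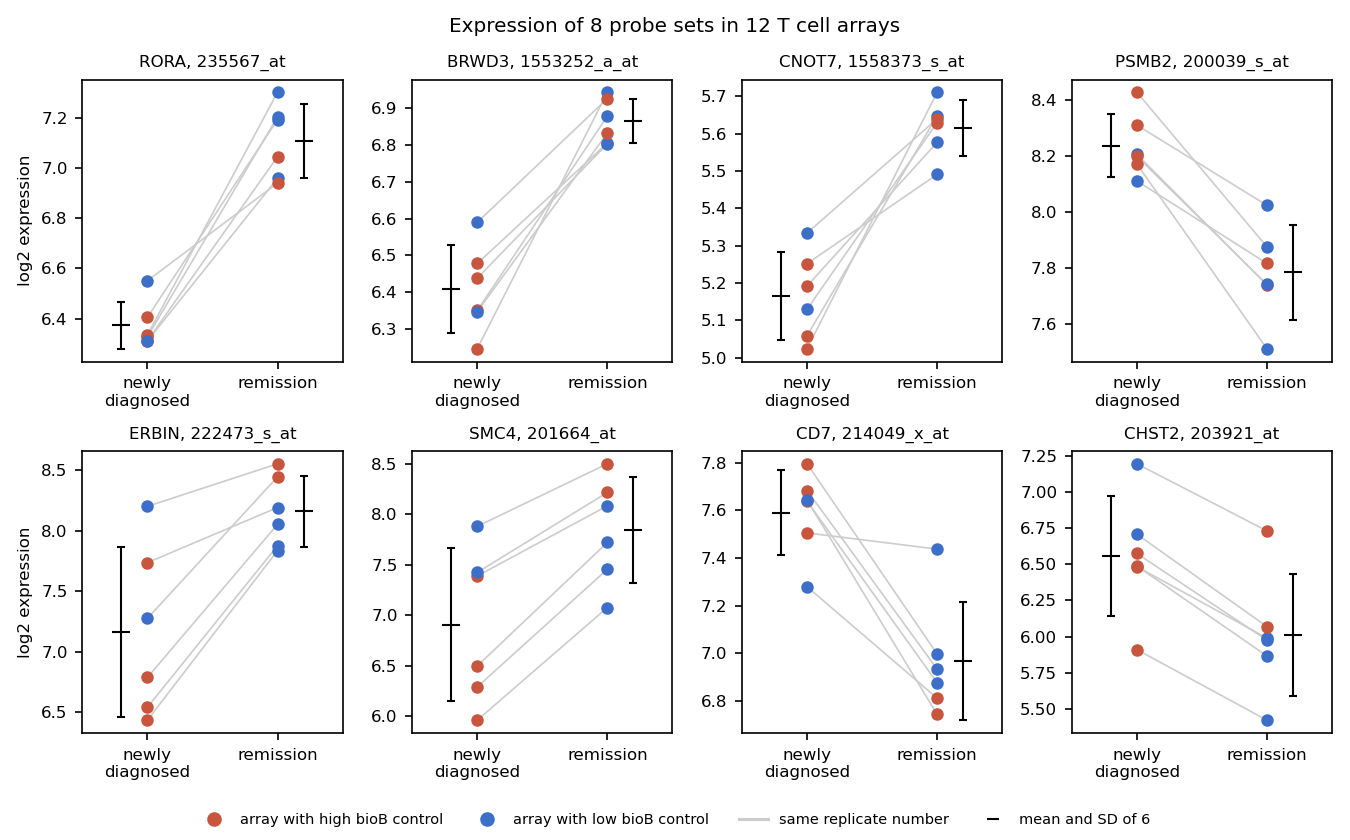
Log2 expression (vertical axis) of 8 probe sets in the newly diagnosed and remission groups, with 1 point per array coloured by its bioB control, lines joining arrays of the same replicate number, and bars for the mean and SD of 6 arrays. RORA separates the groups without overlap, from 6.37 to 7.11, while SMC4 and ERBIN differ by 1.83 and 1.62 within the high bioB arrays against -0.069 and 0.25 within the low ones, comparisons of arrays with different numbers, and by 0.62 to 1.22 and 0.35 to 1.4 within numbers.

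When the replicate number was added as a block, 419 probe sets passed, 370 higher and 49 lower in remission, from 295 and 47 named genes. Among the largest rises were ERBIN, a scaffold protein of cell junctions (0.995, SE 0.16), another RORA probe set (0.98, SE 0.086), RESF1 (0.95, SE 0.088) and SMC4, a condensin subunit (0.94, SE 0.098). RO60 (0.87, SE 0.14), the kinase ROCK1 (0.87, SE 0.11), the alpha-4 integrin ITGA4 (0.87, SE 0.13), ANKRD12 (0.86, SE 0.12), the nuclear pore protein RANBP2 (0.85, SE 0.15) and the cohesin regulator PDS5B (0.85, SE 0.13) also rose. The largest falls were those of UBAP2 (-0.65, SE 0.11), CD7 (-0.62, SE 0.11), CDIPT (-0.62, SE 0.11), CMIP (-0.55, SE 0.098) and the sulfotransferase CHST2 (-0.55, SE 0.048). MAPKAPK3 (-0.55), KLHL6 (-0.54), LARP1 (-0.53), VAT1 (-0.52) and TEX261 (-0.52) also fell. The median difference was 0.51 among the rises and -0.40 among the falls, and all 419 had the same direction in 6 of 6 replicate numbers. The blocked fit favours probe sets whose differences within numbers agree, so this agreement follows from the selection and is no separate support. Other probe sets of some of these genes differed by far less, down to 0.0023 for ERBIN and 0.063 for SMC4 among the rises and to -0.021 for TEX261 and -0.097 for CMIP among the falls. Others went the opposite way, down to -0.095 for ROCK1 and up to 0.13 for KLHL6 and 0.047 for LARP1. Adjusted p-values from limma with Benjamini-Hochberg adjustment were 0.0336 at the lowest, so these calls lie close to the threshold, and no call was left without replicate number 1, 3 or 5, with the batch as a further term, or with a trended and robust variance.

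The 2 batches inferred from the bioB control split every replicate pair. A difference within a batch thus compares arrays of different replicate numbers and holds their differences too. SMC4 differed by 1.83 within the high bioB arrays and by -0.069 within the low ones, ERBIN by 1.62 and 0.25, RANBP2 by 1.35 and 0.078, and ITGA4 by 1.5 and 0.11. CHST2 differed by 0.036 within the high bioB arrays and by -1.14 within the low ones. Within replicate numbers the differences ran from 0.62 to 1.22 for SMC4, 0.35 to 1.4 for ERBIN, 0.27 to 1.22 for RANBP2, 0.38 to 1.26 for ITGA4 and -0.64 to -0.46 for CHST2, each in 1 direction in 6 of 6 numbers. These probe sets were selected by the blocked fit, which favours such agreement. Whether the batches differ in these effects was not tested.

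Among the T helper lists fixed before the data were examined, counted here and below over genes past the expression filter, 5 of 6 Th17 genes (13 are on the array) were higher in remission (median difference 0.38). Over all 13, the mean z-score differed by 0.30 and was higher in 4 of 6 replicate numbers (exact two-sided permutation p = 0.104). IL6ST, the signalling receptor of the interleukin 6 family, stood at 8.47 ± 0.37 and 8.96 ± 0.24 (difference 0.49), and the brightest RORA probe set, which stands for the gene in the list, differed by 0.43. None passed without the block, and 4 passed with the block when adjusted over the list alone, namely AHR (0.34), IL6ST, KLRB1 (0.62) and RORA. Of the 18 TGF-beta signalling genes, 11 were higher (median difference 0.095), with TGFBR1 at 0.43 and SMAD5 at 0.43. With the block, 4 of these passed adjusted over the list alone, SKIL (0.61), SMAD5, TGFBR1 and TGFBR3 (0.77), and 1, TGFBR3, passed over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.0499). Of 26 Th1 and cytotoxic genes, 21 were higher (median difference 0.17), with IL18R1 at 0.54 and STAT4 at 0.40. The mean of all Th1 and cytotoxic genes on the array differed by 0.18, by -0.015 without newly diagnosed 2 and by 0.0053 without remission 3. Of 7 Th2 genes 3 were higher, with GATA3 at -0.37 and IL4R at -0.27. An even split of higher and lower genes is not the baseline for these counts or for those below. Among tested genes of known genomic span, the share higher in remission ran from 20.2% to 63.6% with span, as given below.

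No list as a whole passed limma's camera test after Benjamini-Hochberg adjustment over 26 lists, where the smallest adjusted p was 0.23. Unadjusted p-values under 0.05 were found for Th17 (p = 0.0185, up), TGF-beta signalling (p = 0.0266, up) and platelet markers (p = 0.0242, down) in limma's camera, and with an estimated correlation the smallest adjusted p was 0.736. With the block the smallest adjusted p of limma's camera after Benjamini-Hochberg adjustment was 0.227.

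**Figure D2:**
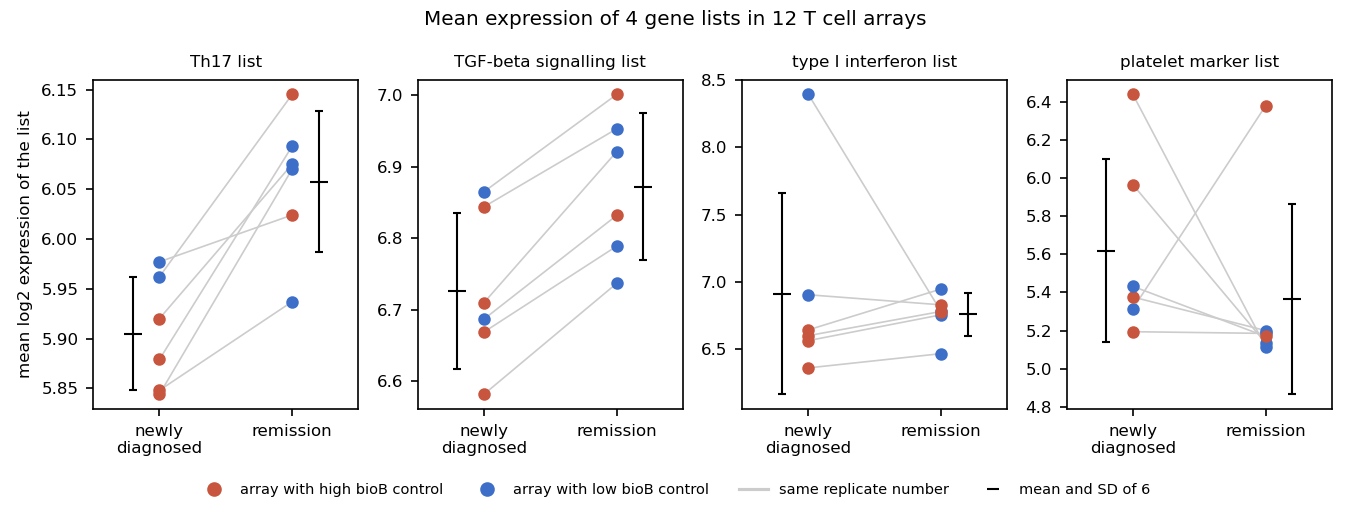
Mean log2 expression (vertical axis) of the Th17, TGF-beta signalling, type I interferon and platelet marker lists in the newly diagnosed and remission groups, with 1 point per array coloured by its bioB control, lines joining the same replicate number, and bars for mean and SD of 6. The interferon mean of newly diagnosed 6 stands at 8.39, and the platelet mean of remission 4 at 6.38.

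Of 15 regulatory T cell genes 7 were higher (median difference -0.068), and PRDM1, a transcriptional repressor that promotes terminal effector differentiation, was at 6.75 ± 0.20 and 7.14 ± 0.29 and passed with the block (limma, Benjamini-Hochberg adjusted p = 0.0498). TNFRSF18 differed by -0.13. Of 14 inhibitory receptor and anergy genes 6 were higher (median difference -0.046), with ITCH at 0.17 and CTLA4 at 0.37. With 1 array left out, CTLA4 ran from 0.28 to 0.58, the latter without newly diagnosed 4. The 5 CTLA4 probe sets ran from 0.0064 to 0.37, so the value given is the largest. FOXP3, the master regulator of regulatory T cells, was measured at 6.55 ± 0.064 and 6.48 ± 0.048, IL2RA at 5.14 ± 0.053 and 5.20 ± 0.13, and TGFB1 at 5.93 ± 0.33 and 5.77 ± 0.28. The TGFB1 difference of -0.154 was -0.0394 without newly diagnosed 6 and -0.0737 without remission 1. For IL2RA the difference of 0.0618 was 0.0195 without remission 2. IL10 lay at 4.85 and 4.82, near the 4.84 median of the unspiked bacterial controls, and was below the expression filter.

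The T cell identity and effector genes did not pass the test in either fit. CD3E stood at 8.22 ± 0.29 and 8.26 ± 0.30, CD4 at 7.53 ± 0.34 and 7.28 ± 0.27, and CD8A at 9.25 ± 0.80 and 9.56 ± 0.21. TBX21, the Th1 transcription factor, stood at 7.03 ± 0.87 and 7.31 ± 0.86, IFNG at 5.26 ± 0.27 and 5.49 ± 0.33, GZMB at 7.59 ± 1.29 and 7.79 ± 1.30, and PRF1 at 9.84 ± 0.99 and 10.06 ± 0.60. GATA3 stood at 8.20 ± 0.24 and 7.83 ± 0.40, TNFAIP3 at 8.34 ± 0.28 and 8.35 ± 0.36, and BACH2 at 7.57 ± 0.30 and 7.67 ± 0.20. Of 63 named probe sets past the threshold in neither fit, leaving out 1 array moved the difference by over 1.5 times for 23 and turned it for 5. These were GZMB (-0.19 without newly diagnosed 2, -0.036 without newly diagnosed 1, -0.18 without remission 3), PRF1 (-0.15) and CD8A (-0.0070) without newly diagnosed 2, and TNFAIP3 and CD3E, whose differences were near 0 (0.0076 and 0.040). TBX21, at 0.28, ran from 0.030 without newly diagnosed 2 to 0.53 without newly diagnosed 3, and CD4, at -0.25, stood at -0.17 without newly diagnosed 6. BACH2, at 0.104, ran from 0.0429 without newly diagnosed 3 to 0.191 without newly diagnosed 5.

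Of 25 T cell receptor signalling genes 8 were higher (median difference -0.092). PTPRC (CD45) differed by 0.50 and PTPN22 by 0.45, and PTPN22 passed with the block adjusted over the list alone. The naive and central memory list had 9 of 16 genes higher (median difference 0.042), with CCR7 at -0.39 and MAL at -0.44. The early activation list had 9 of 23 (median difference -0.030), with JUN at -0.38 (-0.24 without newly diagnosed 2 or remission 4) and NR4A1 at -0.056, and the NF-kappaB list had 8 of 22 (median difference -0.051), with REL at 0.57 and TRAF6 at 0.27. The apoptosis list had 11 of 23 genes higher (median difference -0.039), with CFLAR at 0.25 and BAD at -0.12. The 13 CFLAR probe sets ran from -0.28 to 0.48. The cell cycle list had 18 of 25 (median difference 0.048), with MCM2 at -0.27 and CCNE2 at 0.16. Type I interferon response genes were higher in 9 of 31 cases (median difference -0.23), with IFI6 at -0.31 and LY6E at -0.40 (-0.19 without newly diagnosed 6). The interferon list's mean differed by -0.15 with all arrays and by 0.15 without newly diagnosed 6 (6.61 against 6.76), and its score was higher in remission for 4 of 6 replicate numbers. Cytokine genes were higher in 3 of 10 cases (median difference -0.078), with LTA at -0.33. The glucocorticoid response list had 6 of 16 higher (median difference -0.072), with ZFP36L2 at 0.22 (its 3 probe sets ran from -0.15 to 0.22) and SOCS1 at -0.37.

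Among housekeeping groups, 10 of 25 proteasome genes were higher (median difference -0.037), and PSMB2 passed adjusted over the list alone in both fits and over all probe sets with the block (limma, Benjamini-Hochberg adjusted p = 0.0399), while PSMB5 differed by -0.30. Oxidative phosphorylation genes were higher in 9 of 28 cases (median difference -0.089), with COX5B at -0.34 and NDUFS1 at 0.21 (-0.19 at its other probe set), and ribosomal protein genes in 13 of 23 (median difference 0.020), with RPL35 at -0.30 (-0.18 without remission 4) and RPL6 at 0.25 (0.16 without newly diagnosed 2). Of 13 heat shock genes 7 were higher (median difference 0.075), with BAG3 at -0.20, and CHORDC1 (0.46) and HSPH1 (0.55) passed with the block adjusted over the list alone.

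Markers of other blood cells were present at levels that differed between arrays. Platelet markers were lower in remission in 13 of 14 genes (median difference -0.25), with GP9 at -0.088 and SELP at -0.24, and their mean reached 6.44 in newly diagnosed 2, 5.97 in newly diagnosed 3 and 6.38 in remission 4 against 5.12 to 5.43 elsewhere. The platelet list's mean differed by -0.26, by -0.092 without newly diagnosed 2 and by -0.46 without remission 4. Newly diagnosed 2 also weighed on SELP (-0.12 without it), FCER1G (-0.43), PAX5 (-0.33), HBB (-1.17 with it and -0.57 without) and CFD (-0.066). Newly diagnosed 1 weighed on CAMP (-0.22 without it) and newly diagnosed 5 on SPIB (-0.058). Without those 3 platelet-high arrays no probe set passed in limma and 2442 had an unadjusted p under 0.05, but the called RORA probe set differed by 0.76 (SE 0.086) against 0.73 (SE 0.073) with all arrays, so that its call ended with the 9 arrays left and not with a smaller difference (limma, Benjamini-Hochberg adjusted p = 0.236). The other 4 called probe sets differed by 0.34 to 0.63 there, against 0.37 to 0.66 with all arrays. Monocyte markers were lower in 12 of 17 genes (median difference -0.21), with FCER1G at -0.66 and TYROBP at -0.53, neutrophil markers in 6 of 9 (median difference -0.26), with LCN2 at -0.31 and CAMP at -0.35, and B cell markers in 10 of 12 (median difference -0.16), with PAX5 at -0.52 and SPIB at -0.12. Single arrays weighed on these too. The mean over all markers on the array differed by -0.18 for monocytes and -0.16 for neutrophils, and by -0.039 and -0.048 without newly diagnosed 2, while for monocytes it was -0.10 without remission 1 and -0.30 without remission 4. For B cells it differed by -0.12, by -0.022 to -0.048 without newly diagnosed 5 or remission 1, 2, 3 or 5, by -0.19 without newly diagnosed 3 and by -0.27 without remission 4 or 6. Of 8 NK cell markers 5 were higher, with KLRF1 at 0.29 (0.18 without remission 3), and CD7 passed adjusted over the list alone in both fits. The erythroid list had 2 genes past the expression filter, HBB (6.94 ± 1.59 and 5.77 ± 0.59) and HBM (-0.078), and the adipocyte list 3, among them CFD (-0.17) and CIDEA (-0.052). The adipocyte genes ADIPOQ, LEP, FABP4 and PLIN1 did not exceed 5.03 on any array.

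Scores of the lists, taken as each array's mean z-score, did not differ between groups after adjustment. The smallest exact permutation p was 0.00649 for the adipocyte list (difference -0.84, Benjamini-Hochberg adjusted p = 0.169), followed by exact permutation p = 0.0152 for the erythroid list (difference -0.91, or -0.53 without newly diagnosed 2) and p = 0.0216 for TGF-beta signalling (difference 0.37), the latter higher in 6 of 6 replicate numbers. Of the 15 adipocyte genes on the array only 3 lay past the expression filter. The mean of that list was 5.03 in newly diagnosed and 4.99 in remission arrays, near the floor of 4.84. Its z-score difference of -0.84 thus stands for -0.042 in log2 units. For cytokines the exact permutation p was 0.0476 (difference -0.30, Benjamini-Hochberg adjusted p = 0.31). In log2 units that difference was -0.02, with group means of 5.55 and 5.53. With 1 array left out, the exact permutation p ran from 0.00216 to 0.0952.

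Across genes, the difference moved with the genomic span of the gene. With the genes in 10 bins of equal size by span, the median difference was -0.080 in the shortest bin (median 2.59 kb) 0.076 in bin 9 (median 108 kb) and 0.051 in the longest bin (median 224 kb), so that the trend did not continue there, and the rank correlation across 11691 genes, which are not independent replicates, was 0.34. The slope of each array's deviation on the log10 span was -0.060 ± 0.071 in newly diagnosed and 0.060 ± 0.035 in remission arrays (SD, n = 6 per group, exact two-sided permutation p = 0.00433), a difference of 0.119 that was 0.124 within the high and 0.111 within the low bioB batch. That permutation treats the 12 arrays as independent. With the replicate numbers taken as pairs, the exact two-sided sign flip p was 0.0312, the smallest that 64 sign flips can give. The share of genes higher in remission was 20.2% in the shortest bin, 63.6% in bin 9 and 61.8% in the longest bin. The counts of higher genes given above for each list were not compared with genes of like span. The genes that rose with the block had a median span of 75.7 kb against 28.4 kb for all tested genes, and those that fell 24.5 kb. With this trend removed from each array the called RORA probe set differed by 0.68 and ERBIN by 0.93.

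**Figure D3:**
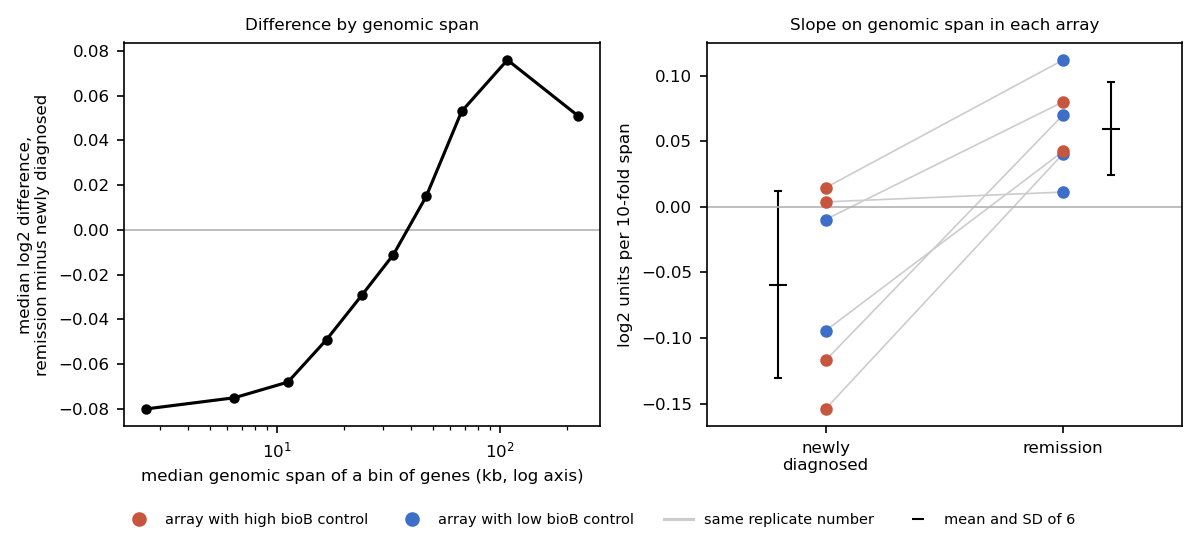
Left, the median log2 difference (remission minus newly diagnosed) of 10 bins of genes against their median genomic span in kb on a log axis, from -0.080 at 2.59 kb to 0.076 at 108 kb and 0.051 at 224 kb. Right, the slope of each array's deviations on span, in log2 units per 10-fold span, with points coloured by bioB control, lines joining the same replicate number, and bars for mean and SD of 6.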

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

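The tests of the interferon and platelet patterns were chosen only after the values had been seen, and both limits in the platelet tests were reworded once after a first look at their values. Under the first wording, any value below the median, a lower share of T cells would have counted as excluded, and the later wording left it open. In 20 of 238 groups of 6 arrays the highest or lowest array stood far from the others; chance gives about 1 in 20 such groups.

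Newly diagnosed 6 had the highest mean of the type I interferon genes (8.39, next in its group 6.90 and next of all arrays 6.95), and its LY6E level was 7.72 against 6.64 for the next array of its group. More monocytes in that array are argued against, since 2 arrays had higher monocyte marker means, with interferon means of 6.60 and 6.83. The hybridisation batch read by the bioB control is argued against too, since 3 of the other 5 arrays of its batch lay below the highest array of the other batch. An interferon response of that child at sampling may be the source and stays untested.

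Platelet markers were high in 3 arrays, remission 4 (6.38, next in its group 5.20) and newly diagnosed 2 (6.44) and 3 (5.97), and SELP reached 5.95 in newly diagnosed 2. Platelets carried along with the T cells are a candidate source, with PPBP at group means of 7.10 and 6.03 and PF4 at 6.41 and 5.76; how the T cells were isolated is not given in the sources used here. The hybridisation batch read by the bioB control is argued against as the whole source, since the other 3 arrays of the high batch lay below the highest array of the low batch. A lower share of T cells with all other cell types raised alike cannot be told apart from this: of 9 means of monocyte, B cell and erythroid markers in those arrays, 3 lay below the median of the other arrays but 0 by over 1 SD, and on mean z-scores 1 did, the erythroid score of remission 4 (-0.977 against a median of -0.215, SD 0.322), from 1 array and genes near the floor. A difference between disease states stays open.

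Newly diagnosed 2 stood apart most often, and it also had the highest actin 3 prime to 5 prime difference (4.82) and high platelet markers. Its erythroid marker mean was 5.67, JUN 9.42, NR4A1 5.39, KLHL6 7.09 and CFD 6.06, each the highest of its group, and CD8A 7.64, PRF1 7.95 and CFLAR 7.99 were each the lowest. Newly diagnosed 3 had the highest GATA3 (8.67), TNFRSF18 (5.41) and BAG3 (5.91) of its group. CTLA4 was highest in newly diagnosed 4 (8.44), and IL10 was lowest in newly diagnosed 5 (4.80). In remission, CD7 was highest in array 5 (7.44), LCN2 highest in array 4 (5.26) and BACH2 lowest in array 3 (7.28).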

How the results depend on the processing

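Of the count of 5 probe sets without the block, 419 passed with the replicate block, 1 with the 75th percentile filter, 2 with quantile normalization and 0 on 1 probe set per gene (limma, 2452 at an unadjusted p under 0.05). Chosen after seeing the data, the bioB term gave 1 (0 without newly diagnosed 6, with 3848 unadjusted), the actin term 2, the length trend removed 1, the arrays without newly diagnosed 2 and remission 5 gave 0 (5112 unadjusted), those without newly diagnosed 2 and 3 and remission 4 gave 0 (2442), the high bioB arrays alone 157 and the low ones alone 0 (2423, of which 814 higher). Leaving out 1 array gave 1 to 1079. The blocked count of 419 became 82 with no filter, 32 with quantile normalization, 0 with a trended and robust variance (6125 unadjusted, lowest adjusted p 0.0508), 1958 with array weights, 0 with the bioB term (6283 unadjusted) and 1 with it without number 6, 0 without numbers 2 and 5 (7154), 0 without numbers 2, 3 and 4 (4251) and 256 with the length trend removed, where the same 21945 probe sets of known span gave 567 before its removal. Leaving out 1 number gave 0 to 446, with 0 without number 1, 3 or 5 and 1 without number 6. Of the lists, 0 passed as reported and with the replicate block, and 6 with no filter, 3 with the block and no filter, 1 with the bioB term and 1 with both (interferon, down, which rests on newly diagnosed 6: without it the list's difference against other genes was 0.11, and 0.067 without number 6 under the block), 1 with the bioB term without newly diagnosed 6 (B cell markers, up), 1 with the block and term without number 6 (Th1 and cytotoxic, up), 5 without newly diagnosed 2 and 3 and remission 4, 9 with the block without numbers 2, 3 and 4, 5 in the high and 6 in the low bioB arrays alone. Leaving out 1 array gave 0 to 1 list (platelet markers down, without remission 4), and leaving out 1 number under the block gave 0 to 4, with 1 without number 2, 4 without number 4 and 1 without number 6. The lists' mean difference against other genes had the other sign in 124 of 1242 combinations of list and setting, over 20 of 26 lists. In 6 of these the list also passed in that direction. This held for B cell markers (0.75), the proteasome (0.24) and interferon (0.24) in the high bioB arrays, for B cell markers also with the bioB term without newly diagnosed 6 (0.38), for the cell cycle (-0.17) in the low ones, and for ribosomal proteins (-0.11) with the block without numbers 2, 3 and 4. List scores gave 0 under all settings run. Fewer arrays lower the power of each such fit; otherwise the cause was not tested. Of 27307 probe sets below the filter 3076 had an unadjusted p under 0.05, 2516 of them lower, at levels near the floor.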

Other observations

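The tests of chance for the counts of calls, and those of the actin control and the batch for the length pattern, were chosen after the results were seen; those of the unadjusted count, the expression level and the blocked calls were set before.

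Among 100 of 462 splits of the 12 arrays into 6 and 6, 3, the real one included, gave at least the 5 calls of the groups, and 2 gave at least its 5219 unadjusted p-values under 0.05 (highest other 6383). Both shares are under 0.05, but only 100 of the 462 splits were run, so the shares are estimates. Other splits went beyond the real one, which therefore is not set apart from other structure among the arrays. The limit of fewer than 5 of 100 splits, set before for the unadjusted count and after for the calls, was met by both. For the reasons above, a random split is still not called excluded as the source of either count. The highest other split gave 1358 calls against the real 5, which points to a structure of the samples. That split put newly diagnosed 1, 2, 3 and 5 with remission 1 and 5, so that it kept the pairs 1, 4, 5 and 6 together. Among the newly diagnosed arrays it followed the bioB batch. Remission arrays did not follow it, since 1 and 5 (low) stood with the high newly diagnosed arrays, and 4 and 6 (high) with the low ones. The GAPDH 3 prime to 5 prime difference ran from 1.49 to 3.11 on the first side and from 0.984 to 1.59 on the other. Whether RNA quality makes up that structure was not tested. A split by bioB batch gave 0 calls in limma and 1931 unadjusted p-values under 0.05. With the block, 1 of the 32 exchanges within pairs, the real one, gave 419 calls, against 0 for the highest other; by unadjusted p under 0.05 the gap was smaller, 6094 against 5045, and the 419 lie close under the threshold.

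Genes of long genomic span were higher in remission, by a slope difference of 0.119 per 10-fold span, higher in 6 of 6 replicate numbers. RNA degradation as read by the actin 3 prime to 5 prime control is argued against, since the difference was 0.126 with that control as a covariate (95% interval 0.0497 to 0.203). So is the hybridisation batch as read by the bioB control, with 0.117 (0.0353 to 0.2). The GAPDH 3 prime to 5 prime difference was 1.9 in newly diagnosed and 1.49 in remission arrays (exact permutation p = 0.271). It was not used as a covariate, so degradation as read by GAPDH stays untested. Dependence on expression level is argued against too, since all 4 groups of genes by expression level kept at least 0.5 of the rank correlation over all genes (0.20 to 0.40 against 0.34). The length trend is not the whole source of the blocked calls, since 256 probe sets passed after its removal. The calls lost are many. The same 21945 probe sets of known span gave 567 before its removal. Of the 419 blocked calls, 369 passed there before and 237 after. In 10 of 10 named rises, the top of the pattern, at least 0.5 of the difference was kept. They were picked as the largest rises (0.85 to 0.995), while the bin medians ran only from -0.080 to 0.076. That share could hardly have come out otherwise, so it decides nothing. The actin control reads 1 kind of RNA damage, so handling, nuclear or unspliced RNA, time, age, treatment and disease state may each be a source and stay untested.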
